A study of Oryza sativa Japonica Group with 18 samples.

How the data were processed

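The deposited files held 1 scanner table for each of 18 arrays and 1 table of log ratios. Each array was a 2-colour Agilent rice array on which RNA from treated seedlings carried Cy5, read in the red channel, and RNA from untreated seedlings carried Cy3, read in the green channel. Spot intensity came from Agilent Feature Extraction 10.5.1.1, per the file headers. The mean spot intensity and the median local background intensity of each channel were used here. The deposited table held log10 ratios of red over green that equalled the log ratio column of the scanner tables, with a largest difference of 0, and was used only as an alternative. The software's own processed signals, already background-subtracted and dye-normalised, were also used only as an alternative.

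Each array carried 45151 spots, of which 1417 were controls, and a further 590 carried planted control sequences. The remaining 43144 spots held 42418 probes. Control spots and spots marked as outliers by the scanner software were left out, and no spot was saturated. Background was corrected with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50. Log2 ratios of red over green were then adjusted within each array by loess, and spots of the same probe were averaged. A probe was kept if it was well above background in either channel on at least 3 of the 18 arrays, which left 35391 probes. The probe with the highest mean log2 intensity stood for each gene, which gave 24515 tested genes of 29864, and 15107 of these had an informative description. Loci and descriptions were those of the array annotation, and the number of loci matched in an outside reference was 0, so no genome positions are given.

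One limma model with a mean for each of the 6 groups was fitted over all 18 arrays, and each comparison was a contrast of these means with empirical Bayes moderation of the spread. P values were adjusted by the Benjamini-Hochberg method over all genes in each comparison, and genes with an adjusted p below 0.05 were counted as changed. No term for the replicate number or the slide was in the model. Every result was also computed with the replicate number as a block and with the slide as a block. Files gave 5 slides. On day 1, replicates 1, 2 and 3 of both groups lay on slides 1, 2 and 3. On day 5 the same held except that sufficient replicate 2 lay on slide 5. On day 10 all 3 starvation arrays lay on slide 4, together with sufficient replicate 1 only, so that the slide block rested on that array for day 10. Sufficient replicates 2 and 3 of day 10 lay on slide 5, so no day 1 array shared a slide with a day 10 array. Slides 1, 2 and 3 were joined to slides 4 and 5 only through sufficient replicate 2 of day 5. With the slide block, day 10 against day 1 and the comparisons with untreated seedlings depended on that link.

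The labels call the replicates biological replicates. Arrays of the same replicate number deviated from their group means together, with correlations across genes of 0.115 to 0.813 in all 45 such pairs, so the number pairs the arrays across groups. On day 10 replicates 1 and 3 were close in the red channel, with an SD of the log2 difference of 0.140 under starvation and 0.177 under sufficient phosphate, against 0.479 to 0.497 for pairs with replicate 2. The highest SD between green channels of 1 number was 0.202. The red difference between 2 replicates repeated over 2 probes of a gene with a correlation across genes of 0.847 for that starvation pair and 0.557 for the sufficient pair, against at most 0.579 for green channels of 1 number. The sufficient pair was not told apart from 1 RNA by this value, but it was by the rank correlation of 0.507 against at most 0.401, by the median absolute deviation of 0.151 against at most 0.141, and by the correlation of at most 0.454 for green channels on the same slides. The starvation pair had a median absolute deviation of 0.121, below 0.141, against 0.0539 for the 1 pair of green channels of 1 number within slide 4. Throughout, n = 3 counts arrays. Genes are not independent replicates. No dyes were swapped, so that a dye effect on a gene cancels between starvation and sufficient phosphate and between days, and does not cancel in a comparison with untreated seedlings.

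Gene lists were fixed before the data were examined, and 28 of 30 had at least 3 measured members and were tested. The lists covered phosphate signalling and SPX proteins, PHT1 phosphate transporters, the PHO1 family, purple acid phosphatases, phosphate scavenging enzymes, membrane lipid remodelling, phosphate-sparing carbon metabolism, iron acquisition, iron storage, nitrogen and sulfur uptake and assimilation, photosystems and light harvesting, the Calvin cycle, chlorophyll synthesis, cytosolic and plastid-type ribosomal proteins, starch and sucrose, phenylpropanoids and flavonoids, diterpenoid phytoalexins, jasmonate synthesis and TIFY proteins, defence proteins, WRKY factors, class III peroxidases, glutathione S-transferases, heat shock proteins, LEA proteins and dehydrins, cell wall loosening, core histones, the circadian clock and root markers. Symbols in the lists came from general knowledge, the array gave only descriptions, and 15 listed loci were left out because their description did not match the symbol. Lists were tested with camera from limma at a preset correlation between genes of 0.01, with p values adjusted over the 28 lists, and again with an estimated correlation. Counts of members that passed are given over all genes and, where a list's count is given and differs, adjusted over the list alone.

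Named genes followed a rule fixed before the data were examined. For each day of starvation against sufficient phosphate they were the 8 largest rises and 8 largest falls among genes past the threshold that had an informative description and arrays that did not overlap between groups, every measured member of the phosphate signalling list, and up to 4 members of each other list by smallest p. Other comparisons took the 5 largest rises and 5 largest falls. Where a group's signal was not well above background, the fold is given as at least a stated value, from the bound on the dim signal. The bound uses the red channel alone and is open to dye bias, and where it exceeds the fold from the log ratios no fold is given.

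In a self-test, 200 genes were given a known change in each of 5 draws. At 2-fold, 74.3% of these were recovered in the day 1 comparison, 75.8% at day 5, 76% at day 10 and 93.6% in the mean of days, against 51.7% for the change of effect from day 1 to day 10. The share of false calls at 2-fold on day 10 was 0.524%, and 6.61% with the replicate block. The draws used noise independent between genes, the same spread in every group and no slide effect. These shares are therefore not the error rate of the real day 10 calls.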

Results

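Rice seedlings of the cultivar Nipponbare, 2 weeks old, were moved to liquid medium without phosphate (starvation) or with phosphate (sufficient) and sampled after 1, 5 and 10 days. Each of the 6 groups had 3 arrays, and every array set a treated sample against untreated seedlings. Between 77.7% and 80.5% of spots were well above background in the red channel and between 76.7% and 80.3% in the green channel. Median spot intensity was 338 to 799 in red and 275 to 406 in green, over median backgrounds of 52.5 to 64 and 22 to 27. The number of arrays limits the precision of every value. Values below are log2 differences with the standard error of the limma fit (SE), and n = 3 arrays in each group throughout. Between starvation and sufficient phosphate, rose and fell mean higher and lower under starvation. They do not tell which group had moved.

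The day 1 comparison asked which transcripts had changed soon after phosphate was withdrawn. A pair of class III peroxidases, enzymes of the cell wall and of hydrogen peroxide metabolism, rose under starvation: Os12g0112000 by 2.12 (SE 0.29, adjusted p = 0.0202) and Os11g0112400 by 1.65 (SE 0.22, adjusted p = 0.0202). Os01g0895200, described by a carbohydrate-binding module and a cytochrome domain of the cellobiose dehydrogenase type, rose by 1.75 (SE 0.27, adjusted p = 0.0397). A disease resistance family gene, Os11g0689100, rose by 0.80 (SE 0.09, adjusted p = 0.00369). These were 4 of the 7 genes that changed by limma, 6 higher and 1 lower. The other 3, Os01g0895300 at 2.03, Os11g0490100 at 1.37 and Os03g0736900 at -1.46, were named after their values were seen. All 7 also passed at days 5 and 10 in the same direction. The 7 genes became 33 with the replicate block and 5 with the slide block, which left out Os01g0895300 and Os03g0736900. At unadjusted p below 0.05 there were 1822 genes. Leaving out 1 array gave 2 to 8 genes, and the share that was higher, 85.7%, was 75% with the deposited log ratios.

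On day 1 the phosphate-related lists held 0 members past the threshold by limma, while some differed as groups by camera. Adjusted over the list alone, 1 phosphate scavenging enzyme gene rose and 1 fell. The 7 measured PHT1 transporters, which carry phosphate into cells, had a median of 0.67 (adjusted p = 0.0309 by camera; adjusted p = 0.572 with an estimated correlation; adjusted p = 0.0598 with the slide block). Os03g0150800 stood at 0.84 (SE 0.38, adjusted p = 0.653) and Os10g0444700 at 1.05 (SE 0.54, adjusted p = 0.695). The 13 purple acid phosphatases, which release phosphate from organic compounds, had a median of 0.16 (adjusted p = 0.029 by camera; adjusted p = 0.572 with an estimated correlation). Within that family Os03g0238600 stood at 0.70 (SE 0.21, adjusted p = 0.509) and Os11g0151700 at 1.15 (SE 0.59, adjusted p = 0.694). The 13 measured members of the phosphate signalling list had a median of 0.03 and a camera direction of down (adjusted p = 0.917). Among them the 3 SPX genes Os07g0614700, Os03g0406100 and Os02g0202200 stood at 0.03, 0.01 and 0.06.

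Other lists that differed by camera on day 1 were led by photosynthesis and iron. Photosystem and light harvesting genes were lower, with a median of -0.46 over 46 genes (adjusted p = 6.61e-08; adjusted p = 0.572 with an estimated correlation). Plastid-type ribosomal proteins had a median of -0.33 over 47 genes (adjusted p = 6.98e-07; adjusted p = 0.546 with an estimated correlation). Within slides 1, 2 and 3 the photosystem medians were -0.19, -0.13 and -1.15, and the plastid ribosomal medians were -0.19, 0.02 and -0.72. No member of either list passed, and Os08g0347500, an oxygen-evolving complex protein of photosystem II, stood at -0.43 (SE 0.15, adjusted p = 0.551). Iron acquisition genes were lower, with a median of -0.70 over 14 genes (adjusted p = 0.00328; adjusted p = 0.546 with an estimated correlation), and 1 fell when adjusted over the list alone. The iron transporter gene Os03g0667500 (IRT1) stood at -1.69 (SE 0.59, adjusted p = 0.566) and the regulator Os03g0379300 (IRO3) at -1.31 (SE 0.34, adjusted p = 0.402). The 4 measured genes of iron storage, whose descriptions name ferritin or a vacuolar iron transporter, had a median of 0.45 (adjusted p = 0.0173; adjusted p = 0.546 with an estimated correlation). Class III peroxidases had a median of 0.20 over 110 genes, of which 2 rose (adjusted p = 0.00169; adjusted p = 0.546 with an estimated correlation). LEA proteins and dehydrins had a median of 0.11 over 17 genes (adjusted p = 0.00328; adjusted p = 0.546 with an estimated correlation). The dehydrin Os11g0454200 stood at 1.88 (SE 0.42, adjusted p = 0.37), and 2 members rose when adjusted over the list alone. Cell wall loosening genes had a median of 0.12 over 48 genes, 2 of which rose when adjusted over the list alone (adjusted p = 0.029; adjusted p = 0.546 with an estimated correlation). Glutathione S-transferases had a median of 0.18 over 56 genes (adjusted p = 0.0481; adjusted p = 0.755 with an estimated correlation; adjusted p = 0.0631 with the slide block). The 5 root markers had a median of -0.25 and passed as lower only with the replicate block (adjusted p = 0.0195; adjusted p = 0.534 with the block and an estimated correlation), as did their member Os07g0257200, a metal transporter, at -1.05 (adjusted p = 0.00833 with the block). The remaining lists did not pass on day 1.

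After 5 days the largest differences were in genes of iron uptake, which were lower under starvation. The nicotianamine synthase gene Os03g0307200, which makes the metal chelator nicotianamine, fell by 5.40 (SE 1.18, adjusted p = 0.0299) and its relative Os03g0307300 fell by 5.27 (SE 1.14, adjusted p = 0.0285). The oligopeptide transporter gene Os02g0650300 fell by 5.33 (SE 0.69, adjusted p = 0.00175), IRT1 fell by 4.15 (SE 0.59, adjusted p = 0.0033), and the nicotianamine aminotransferase gene Os02g0306400area fell by 4.06 (SE 0.59, adjusted p = 0.00402). Of the 14 measured iron acquisition genes 10 fell and 0 rose, with a median of -2.46 (adjusted p = 1.54e-09 by camera; adjusted p = 0.151 with an estimated correlation). The medians were -2.79 and -1.76 within the 2 slides that held both groups, and 5 genes fell with the slide block, in which both nicotianamine synthase genes did not pass (adjusted p = 0.0659 and 0.0739). The regulators IRO3 and Os01g0952800 (IRO2) fell by 2.31 (SE 0.34, adjusted p = 0.00454) and 2.23 (SE 0.34, adjusted p = 0.00502; adjusted p = 0.0686 with the slide block). The 4 genes of the iron storage list had a median of 0.67 (adjusted p = 0.00285 by camera; adjusted p = 0.151 with an estimated correlation), against -0.02 with median centring of the arrays. None of these 4 genes passed over all genes and 3 rose when adjusted over the list alone, and Os11g0106700 stood at 0.83 (SE 0.22, adjusted p = 0.0602; adjusted p = 0.0313 with the replicate block).

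Some phosphate-related genes passed on day 5. Os06g0603600, known as SPX1 but left out of the lists because the array describes it as Ids4-like, rose by 2.73 (SE 0.27, adjusted p = 0.000297). The SPX gene Os02g0202200 rose by 1.62 (SE 0.38, adjusted p = 0.043; adjusted p = 0.129 with the slide block). The ubiquitin-conjugating enzyme gene Os05g0557700, listed as PHO2, a repressor of phosphate uptake, fell by 1.17 (SE 0.20, adjusted p = 0.00923; adjusted p = 0.103 with the slide block). Of the 13 signalling genes 1 rose and 1 fell (2 and 1 when adjusted over the list alone, 3 and 1 with the replicate block), and the list did not pass (adjusted p = 0.113 by camera). Not past the threshold were Os07g0614700 at 1.29 (adjusted p = 0.325) and Os03g0406100 (adjusted p = 0.337), which was not well above background under sufficient phosphate. Os04g0573000 at 0.96 and Os06g0493600, not well above background in either group, passed only with the replicate block (adjusted p = 0.0378 and 0.0201). The purple acid phosphatase Os03g0238600 rose by 1.44 (SE 0.21, adjusted p = 0.00454) and was the 1 gene of 13 that rose, against 3 with the replicate block. The 7 PHT1 transporters had a median of 0.75 and 0 members past the threshold by limma, 3 with the replicate block, under which the list passed (adjusted p = 0.0445; adjusted p = 0.813 with the block and an estimated correlation). The glycerophosphodiester phosphodiesterase gene Os02g0514500, of phospholipid breakdown, rose by 1.90 (SE 0.35, adjusted p = 0.013; adjusted p = 0.11 with the slide block) and was the 1 of 36 lipid genes that rose, against 2 with the replicate block.

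Phosphate-sparing carbon metabolism genes had a median of 0.32 on day 5 over 18 genes (adjusted p = 0.00388 by camera; adjusted p = 0.791 with an estimated correlation), against -0.10 with median centring. In that list Os06g0247500, the beta subunit of the pyrophosphate-dependent phosphofructokinase, rose by 0.65 (SE 0.14, adjusted p = 0.027; adjusted p = 0.0946 with the slide block) but stood at -0.21 with median centring. With the replicate block 4 genes of the list rose. The alternative oxidase Os02g0318100, of the mitochondrial bypass of the cytochrome pathway, stood at 3.09 (SE 0.97, adjusted p = 0.109; adjusted p = 0.0222 with the replicate block). Photosystem genes had a median of -0.62 over 46 genes, with medians of -0.64 and -0.71 within slides (adjusted p = 2.93e-06 by camera; adjusted p = 0.791 with an estimated correlation). In that list 1 gene fell, Os08g0347500, by 0.80 (SE 0.15, adjusted p = 0.0129; adjusted p = 0.0896 with the slide block). Plastid-type ribosomal proteins had a median of -0.45 and passed as lower (adjusted p = 0.00388 by camera; adjusted p = 0.791 with an estimated correlation; adjusted p = 0.0555 with the replicate block). Of 47 members 1 fell over all genes, and 23 fell and 3 rose when adjusted over the list alone. Cytosolic ribosomal proteins had a median of 0.18 over 157 genes with 0 past the threshold by limma (adjusted p = 2.82e-07 by camera; adjusted p = 0.791 with an estimated correlation), against -0.67 with median centring. WRKY transcription factors had a median of -0.18, and 1 of 62 fell, 5 when adjusted over the list alone and 8 with the replicate block (adjusted p = 0.0351 by camera; adjusted p = 0.791 with an estimated correlation). That gene, Os01g0750100 (WRKY31), fell by 0.50 (SE 0.11, adjusted p = 0.0323; adjusted p = 0.152 with the slide block).

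Other genes with the largest rises on day 5 were a multicopper oxidase, Os01g0127000, at 3.48 (SE 0.74, adjusted p = 0.0272), and the P450 genes Os11g0138300 at 2.89 and Os12g0134900 at 2.35. A glycosyl transferase, Os01g0142300, rose by 2.70 (SE 0.37, adjusted p = 0.00242) and Wali7, Os12g0145100, by 2.46. Also high were a major facilitator protein, Os08g0156600, at 2.32 (SE 0.22, adjusted p = 0.000201) and a stress-induced protein, Os02g0609200, at 2.05. With the slide block the multicopper oxidase, both P450 genes, Wali7 and the stress-induced protein did not pass (adjusted p = 0.069, 0.121, 0.147, 0.191 and 0.133). The other largest falls were the antiporter Os12g0132500 at -4.14 (SE 0.71, adjusted p = 0.0092) and Os01g0871600 at -3.72 (adjusted p = 0.0779 with the slide block). A ribose 5-phosphate isomerase family gene, Os04g0306400, stood at -3.61 (SE 0.57, adjusted p = 0.00598). Jasmonate synthesis genes included 3 that fell of 32, allene oxide synthase Os02g0218800 by 1.00 (SE 0.15, adjusted p = 0.005) and the lipoxygenases Os12g0559200 and Os12g0560200 by 1.01 and 0.80, none of which passed with the slide block. Adjusted over the list alone, 3 fell and 1 rose. A Rubisco small subunit gene, Os12g0291400, fell by 1.63 (SE 0.33, adjusted p = 0.0215; adjusted p = 0.123 with the slide block). The Calvin cycle list, with a median of -0.05 and a mean of -0.25, had a camera direction of up (adjusted p = 0.906). Class III peroxidases had a median of -0.04 and a camera direction of up (adjusted p = 0.467), with Os12g0112000 and Os11g0112400 higher by 1.87 and 1.45 (adjusted p = 0.00547 each). Expansin 4, Os04g0583500, rose by 0.68 (SE 0.13, adjusted p = 0.0162; adjusted p = 0.11 with the slide block) but stood at -0.17 with median centring.

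In all, 559 genes changed on day 5, 97 higher and 462 lower, and 213 of them by at least 2-fold. The count was 2549 with the replicate block and 104 with the slide block, of which 97 were shared, and leaving out 1 array gave 91 to 824. The share that was higher was 17.4%, against 37.5% with the software's processed signals and with the deposited log ratios, 36.7% without background correction and 7.77% with median centring, which moved the median of all genes by -0.28. In 1 changed gene, probes changed in opposite directions. All lists not named for day 5 did not pass.

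**Figure D1:**
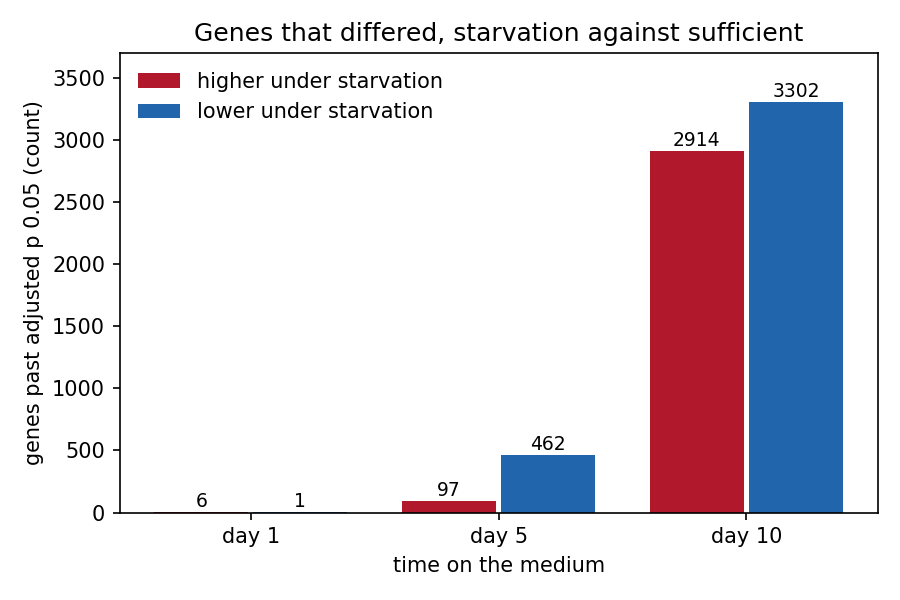
Bars give the number of genes with an adjusted p below 0.05 in starvation against sufficient phosphate (y axis, count) on each day (x axis), separately for genes higher and lower under starvation. The counts were 6 and 1 on day 1, 97 and 462 on day 5, and 2914 and 3302 on day 10.

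After 10 days phosphate-related genes were among the largest rises. The SPX genes Os07g0614700 and Os03g0406100, whose family senses phosphate status, rose by 4.14 (SE 0.66, adjusted p = 0.000652) and 3.65 (SE 0.65, adjusted p = 0.00131). Their relatives Os10g0392600 and Os02g0202200 rose by 3.36 (SE 0.61, adjusted p = 0.00157) and 2.54 (SE 0.38, adjusted p = 0.000433). The Ids4-like gene Os06g0603600 rose by 3.83 (SE 0.27, adjusted p = 4.32e-06), and Os05g0557700, listed as PHO2, fell by 1.77 (SE 0.20, adjusted p = 6.38e-05). Of the 13 signalling genes 5 rose and 3 fell, 4 and 1 with the slide block, and the list as a group did not pass (median 0.32, adjusted p = 0.192 by camera). The smaller changes were Os06g0493600 at 0.53 (adjusted p = 0.0025, at least 1.37-fold), Os03g0329900, listed as PHR1, at -0.23 (adjusted p = 0.0171) and Os03g0650900 at -0.46 (adjusted p = 0.0237). None of these 3 passed with the slide block (adjusted p = 0.0747, 0.191 and 0.0593). Os02g0809800 stood at 0.32 and passed only with the replicate block (adjusted p = 0.034), and Os02g0678200 at 0.33, Os07g0438800 at -0.15, Os03g0827500 at 0.03 and Os04g0573000, not well above background under starvation, did not pass.

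Of the 7 PHT1 transporters on day 10, 3 rose, 5 when adjusted over the list alone and with the replicate block, and 1 with the slide block. Os08g0564000 rose by 2.57 (SE 0.46, adjusted p = 0.00143), Os03g0150800 by 1.49 (SE 0.38, adjusted p = 0.011) and Os10g0444600 by 1.71 (SE 0.50, adjusted p = 0.0229). The last 2 did not pass with the slide block (adjusted p = 0.13 and 0.183). The list median was 1.49 (adjusted p = 0.0234 by camera; adjusted p = 0.621 with an estimated correlation; adjusted p = 0.135 with the slide block). Of the 13 purple acid phosphatases 5 rose, 3 with the slide block, with a median of 0.41 (adjusted p = 0.0122 by camera; adjusted p = 0.611 with an estimated correlation; adjusted p = 0.0849 with the slide block). They included Os03g0238600 at 2.34 (SE 0.21, adjusted p = 1.64e-05), Os12g0637100 at 1.92 (SE 0.30) and Os11g0151700 at 2.86 (SE 0.59; adjusted p = 0.0806 with the slide block). Os10g0116800, not well above background under sufficient phosphate, also rose (adjusted p = 0.000289). Among 11 other phosphate scavenging enzymes 4 rose, and 5 rose and 2 fell when adjusted over the list alone (median 0.36, adjusted p = 0.0171 by camera; adjusted p = 0.532 with an estimated correlation). The haloacid dehalogenase-like hydrolase Os06g0109500 rose by 1.24 (SE 0.10, adjusted p = 1.02e-05) and the T2 ribonuclease Os07g0630400, of RNA breakdown, by 2.03 (SE 0.27, adjusted p = 0.000204). The PHO1 list was not tested, since the array descriptions of its 3 loci did not name the family, and Os02g0809800 and Os06g0493600, described as SPX genes, were counted in the signalling list.

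Genes of membrane lipid remodelling, by which phospholipids are replaced with lipids free of phosphate, had 11 rises and 2 falls among 36 on day 10, 5 and 0 with the slide block. There were 5 falls when adjusted over the list alone (median 0.12, adjusted p = 0.0171 by camera; adjusted p = 0.532 with an estimated correlation). A monogalactosyldiacylglycerol synthase gene, Os08g0299400, which makes galactolipid, rose by 4.38 (SE 0.82, adjusted p = 0.00185; adjusted p = 0.0537 with the slide block). The phosphodiesterase genes Os03g0603600 and Os02g0514500 each rose by 2.91 (SE 0.33 and 0.35), and the phospholipase D gene Os06g0649900 rose by 1.20 (SE 0.16). Phosphate-sparing carbon metabolism did not pass (4 rose, 5 when adjusted over the list alone, 1 fell, adjusted p = 0.179 by camera; 8 rose with the replicate block, 2 with the slide block), with Os06g0247500 higher by 0.96 (SE 0.14, adjusted p = 0.000319). In the same list pyruvate phosphate dikinase Os03g0432100 fell by 1.34 (SE 0.30, adjusted p = 0.00559; adjusted p = 0.0666 with the slide block).

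**Figure D2:**
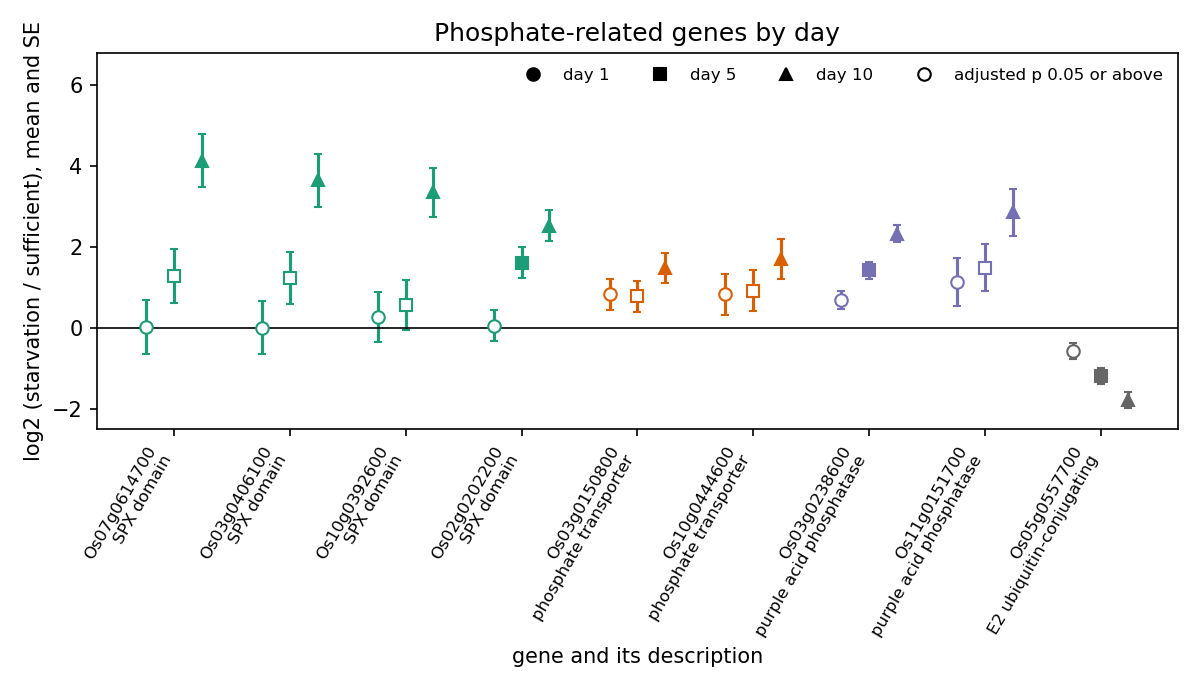
Points are log2 differences between starvation and sufficient phosphate (y axis) for 9 phosphate-related genes (x axis) on days 1, 5 and 10, with bars for 1 SE and n = 3 arrays in each group, open where the adjusted p was 0.05 or above. The SPX gene Os07g0614700 stood at 0.03, 1.29 and 4.14 on the 3 days.

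Iron acquisition genes stayed lower on day 10. Of the 14, 10 fell and 0 rose (1 rose when adjusted over the list alone, 9 fell with the slide block). The median was -2.69, and -3.14 within slide 4 (adjusted p = 3.09e-05 by camera; adjusted p = 0.492 with an estimated correlation). The oligopeptide transporter Os02g0650300 fell by 6.37 (SE 0.69, adjusted p = 5.13e-05), and the nicotianamine synthase genes Os03g0307300 and Os03g0307200 stood at -6.01 (SE 1.14) and -5.90 (SE 1.18). The antiporter Os11g0134900, listed as the phytosiderophore exporter TOM1, fell by 4.56 (SE 0.61, adjusted p = 0.000189). The metal transporter Os07g0258400 fell by 4.42 (SE 0.57, adjusted p = 0.000143) and Os03g0237100, listed as DMAS1 of phytosiderophore synthesis, fell by 4.24 (SE 0.59, adjusted p = 0.00024). The regulator IRO3 fell by 2.82 (SE 0.34, adjusted p = 9.77e-05) and IRO2, not well above background under starvation, also fell (adjusted p = 0.000188). All 4 genes of the iron storage list rose (median 0.90, adjusted p = 0.0059 by camera; adjusted p = 0.492 with an estimated correlation). The list included the ferritins Os11g0106700 at 1.12 (SE 0.22, adjusted p = 0.00237) and Os12g0106000 at 1.05 (SE 0.22, adjusted p = 0.00321). The 5 root markers had a median of -0.24 and 0 past the threshold by limma (adjusted p = 0.648 by camera).

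Photosynthesis lists passed as higher on day 10 by camera, a difference carried by replicates 1 and 3. Of the 46 photosystem and light harvesting genes 7 rose and 1 fell, 5 and 1 when adjusted over the list alone (median 0.64, adjusted p = 0.000181 by camera; adjusted p = 0.706 with an estimated correlation). The median within slide 4 was 1.29. The photosystem II protein PsbS, Os01g0869800, which protects against excess light, rose by 2.46 (SE 0.45, adjusted p = 0.00153). Os04g0690800 rose by 1.57 (SE 0.42, adjusted p = 0.014), while the assembly factor Os06g0729500 fell by 0.75 (SE 0.16, adjusted p = 0.00416; adjusted p = 0.0707 with the slide block). Against untreated seedlings the photosystem medians were 0.17, 0.57 and 0.42 in starvation replicates 1, 2 and 3 and -0.97, 0.82 and -0.75 in the sufficient ones, so replicate 2 went the other way. In replicate 2 the Calvin cycle medians were 0.04 in both groups, and those of chlorophyll synthesis were 0.13 under starvation and 0.17 under sufficient phosphate. Of 24 Calvin cycle genes 5 rose, 12 with the replicate block and 2 with the slide block (median 0.41, adjusted p = 0.0059 by camera; adjusted p = 0.532 with an estimated correlation). The Rubisco small subunit gene Os12g0274700 rose by 2.57 (SE 0.80, adjusted p = 0.0296; adjusted p = 0.06 with the slide block). Of 13 chlorophyll synthesis genes 2 rose, 1 when adjusted over the list alone and 5 with the replicate block (median 0.32, adjusted p = 0.0171 by camera; adjusted p = 0.621 with an estimated correlation). That list did not pass without sufficient replicate 1 (adjusted p = 0.0745) or 3 (adjusted p = 0.0549). Os06g0132400, a magnesium-protoporphyrin methyltransferase, rose by 1.00 (SE 0.22, adjusted p = 0.0053). The early light-inducible protein Os07g0178800 rose by 3.86 (SE 0.48, adjusted p = 0.000108). Cytosolic ribosomal proteins had 7 rises and 2 falls among 157, 0 and 1 when adjusted over the list alone and 82 and 6 with the replicate block. They passed as a group (median 0.24, adjusted p = 0.00117 by camera; adjusted p = 0.762 with an estimated correlation), but not without starvation replicate 2 (adjusted p = 0.066) or sufficient replicate 3 (adjusted p = 0.0952). Plastid-type ribosomal proteins had 7 rises and 4 falls among 47, 6 and 2 when adjusted over the list alone (adjusted p = 0.169 by camera), and passed as higher with the slide block (adjusted p = 0.00204). That value used the preset correlation, and no list passed on day 10 with an estimated one.

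**Figure D3:**
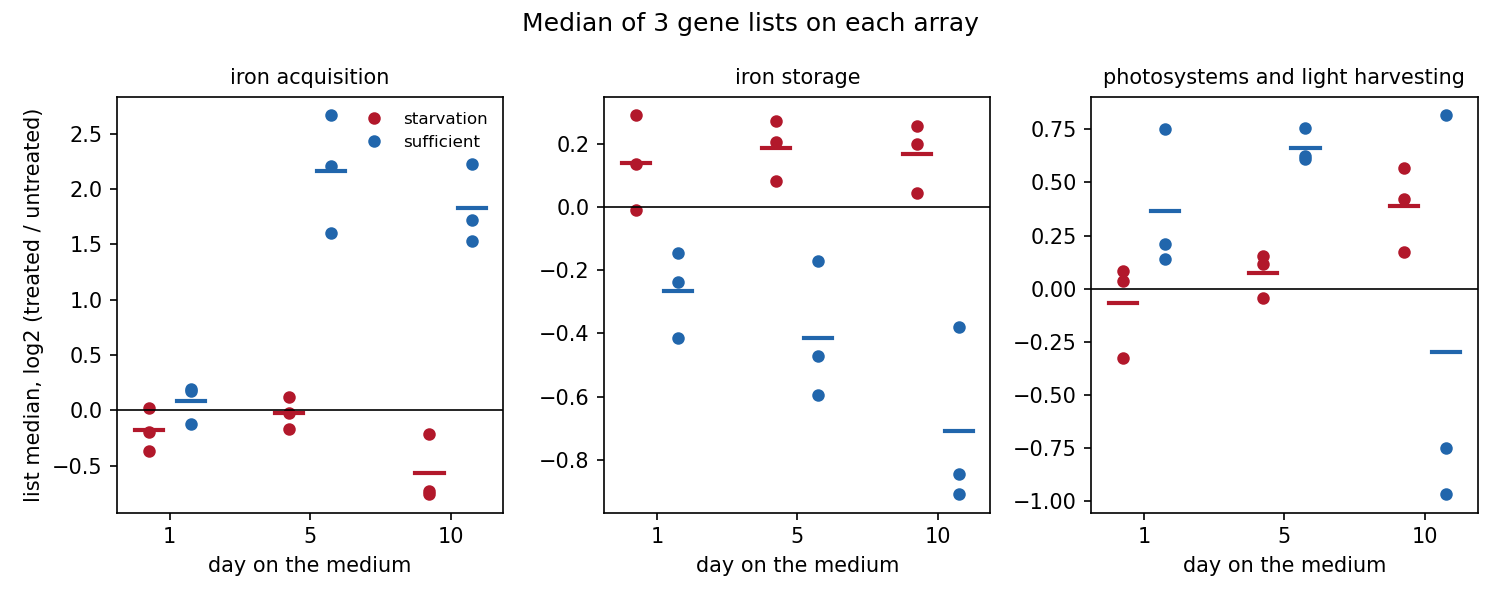
Points are the median log2 ratio of treated over untreated seedlings (y axis) of the iron acquisition, iron storage and photosystem lists on each of the 18 arrays, by day (x axis) and treatment, and lines are group means. The sufficient arrays of day 10 ran from -0.97 to 0.82 for the photosystem list.

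Phenylpropanoid, WRKY, peroxidase and cell wall lists passed on day 10 by camera. Of 52 phenylpropanoid and flavonoid genes 13 rose and 5 fell, 15 and 5 when adjusted over the list alone and 8 and 5 with the slide block (median 0.34, adjusted p = 0.0059 by camera; adjusted p = 0.621 with an estimated correlation; adjusted p = 0.257 with the slide block). Phenylalanine ammonia-lyase Os12g0520200, the entry enzyme of the pathway, rose by 3.93 (SE 0.46, adjusted p = 7.47e-05) and chalcone isomerase Os11g0116300 by 2.14 (SE 0.23, adjusted p = 4.62e-05). Cinnamoyl-CoA reductase Os06g0623600 fell by 1.29 (SE 0.16, adjusted p = 0.000121). Of 62 WRKY factors 18 fell, 20 when adjusted over the list alone, and 0 rose (median -0.33, adjusted p = 0.00128 by camera; adjusted p = 0.532 with an estimated correlation). WRKY10, Os01g0186000, stood at -1.31 (SE 0.24, adjusted p = 0.00163) and WRKY31 at -0.75 (SE 0.11, adjusted p = 0.000331). Of 110 class III peroxidases 26 rose and 7 fell, 27 and 7 when adjusted over the list alone and 44 and 15 with the replicate block (median 0.39, adjusted p = 0.00417 by camera; adjusted p = 0.532 with an estimated correlation). Os06g0274800 rose by 2.53 (SE 0.34) and Os12g0112000 by 2.09 (SE 0.29). Of 48 cell wall loosening genes 8 rose and 3 fell, 20 and 4 with the replicate block (median 0.28, adjusted p = 0.027 by camera; adjusted p = 0.532 with an estimated correlation). Expansin 4, Os04g0583500, stood at 0.94 (SE 0.13) and the expansin family gene Os10g0542400 at -1.98 (SE 0.33). An abscisic acid and water deficit induced protein gene, Os04g0423400, rose by 5.10 (SE 0.45, adjusted p = 1.26e-05). Nodulin 21, Os04g0538400, rose by 5.20 (SE 1.03, adjusted p = 0.00277) and the glycosyl transferase Os01g0142300 by 4.22 (SE 0.37, adjusted p = 1.26e-05). The F-box gene Os06g0594400 fell by 4.96 (SE 0.61, adjusted p = 0.000111) and the antiporter Os12g0132500 by 4.58 (SE 0.71, adjusted p = 0.000509).

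The remaining lists did not pass on day 10 by camera, although single members changed. Starch and sucrose genes had 7 rises and 11 falls among 46, with sucrose-phosphate synthase Os11g0236100 at 2.31 (SE 0.27), granule-bound starch synthase Os07g0412100 at 2.17 (SE 0.37) and the invertase Os01g0332100 at -1.22 (SE 0.20). Nitrogen genes had 3 rises and 6 falls among 37, with the ammonium transporter Os02g0550800 at 1.66 (SE 0.33), and sulfur genes 3 rises and 2 falls among 10, with the sulfate transporter Os03g0161200 at 1.15 (SE 0.17). Jasmonate genes had 7 rises and 1 fall among 32, with the lipoxygenase Os04g0456700 at 2.11 (SE 0.21), and defence proteins 11 rises and 8 falls among 94, with the trypsin inhibitor Os03g0823400 at -2.37 (SE 0.28). Glutathione S-transferases had 9 rises and 2 falls among 56 (adjusted p = 0.0548), with Os10g0530500 at 1.93 (SE 0.34), and heat shock proteins 17 rises and 18 falls among 126 (2 and 10 with the slide block), with the DnaJ gene Os06g0716100 at -2.99 (SE 0.36). LEA proteins had 2 rises and 2 falls among 17, 2 and 6 with the replicate block, and core histones 1 rise and 3 falls among 44. Adjusted over the list alone, rises and falls were 9 and 13 for starch and sucrose, 4 and 2 for sulfur, 10 and 8 for defence, 8 and 1 for glutathione S-transferases, 18 and 18 for heat shock proteins, and 0 and 3 for histones. With the slide block rises and falls were 5 and 3 for starch and sucrose, 2 and 1 for nitrogen, 3 and 1 for jasmonate, and 3 and 1 for glutathione S-transferases. With the replicate block they were 12 and 13 for starch and sucrose, 6 and 8 for nitrogen, 5 and 2 for sulfur, 21 and 18 for defence, 31 and 25 for heat shock proteins, 13 and 4 for glutathione S-transferases and 7 and 5 for histones. Of 7 clock genes Os01g0971800, listed as LUX, rose by 0.83 (SE 0.22), while Os09g0532400, listed as PRR95, and Os08g0157600, listed as LHY, fell by 0.65 (SE 0.18) and 0.67 (SE 0.21), the last 2 not with the slide block. Of the 2 measured diterpenoid phytoalexin genes, too few to test as a list, the kaurene synthase Os02g0278700 rose by 0.35 (SE 0.09, at least 1.27-fold), but not with the slide block (adjusted p = 0.136).

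In all, 6216 genes changed on day 10, 2914 higher and 3302 lower, and 1391 of them by at least 2-fold. The count was 10113 with the replicate block and 3380 with the slide block, of which 2926 were shared, 4045 without starvation replicate 3, 1293 with median centring (636 higher, 657 lower), 2851 with only the arrays compared, and 2765 with replicates 1 and 3 averaged in both groups. In 3 changed genes, probes changed in opposite directions.

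Averaged over the 3 days, the multicopper oxidase Os01g0127000 rose by 3.27 (SE 0.43, adjusted p = 0.000133), the alternative oxidase Os02g0318100 by 3.06 (SE 0.56, adjusted p = 0.00147) and Nodulin 21 by 2.93 (SE 0.60, adjusted p = 0.00281). The glycosyl transferase Os01g0142300 rose by 2.61 (SE 0.21, adjusted p = 7.24e-06) and a sodium transporter gene of the HKT type, Os06g0701700, by 2.53 (SE 0.46, adjusted p = 0.00138). The oligopeptide transporter Os02g0650300 fell by 4.43 (SE 0.40, adjusted p = 1.19e-05), the nicotianamine synthase genes Os03g0307300 and Os03g0307200 by 4.08 and 4.07, the antiporter Os12g0132500 by 3.11 and the F-box gene Os06g0594400 by 3.07. Of the iron acquisition genes 10 of 14 fell and 0 rose (adjusted p = 2.83e-06 by camera; adjusted p = 0.328 with an estimated correlation). All 4 iron storage genes rose (adjusted p = 0.00394; adjusted p = 0.308 with an estimated correlation). PHT1 transporters had 5 rises among 7 (adjusted p = 0.0236; adjusted p = 0.611 with an estimated correlation; adjusted p = 0.0725 with the slide block). Purple acid phosphatases had 5 among 13, 6 when adjusted over the list alone (adjusted p = 0.0146; adjusted p = 0.611 with an estimated correlation; adjusted p = 0.0621 with the slide block). Lipid remodelling had 10 rises and 3 falls (adjusted p = 0.0244; adjusted p = 0.611 with an estimated correlation). Phosphate-sparing carbon metabolism had 6 and 1 (adjusted p = 0.0481; adjusted p = 0.611 with an estimated correlation; adjusted p = 0.0769 with the slide block). Adjusted over the list alone, rises and falls were 2 and 19 for WRKY factors, 23 and 11 for peroxidases and 6 and 2 for glutathione S-transferases. Over all genes WRKY factors had 1 rise and 19 falls (adjusted p = 0.00557), peroxidases 22 rises and 11 falls (adjusted p = 0.0128) and cell wall loosening genes 6 and 3 (adjusted p = 0.0477), each with adjusted p = 0.611 with an estimated correlation. Cytosolic ribosomal proteins had 7 rises and 1 fall (0 and 1 when adjusted over the list alone; adjusted p = 0.000517; adjusted p = 0.802 with an estimated correlation; 79 and 4 with the replicate block). Glutathione S-transferases had 7 and 3 (adjusted p = 0.0419; adjusted p = 0.802 with an estimated correlation; adjusted p = 0.0926 with the slide block). With the replicate block rises and falls were 41 and 15 for peroxidases, 17 and 5 for cell wall loosening and 15 and 5 for glutathione S-transferases. LEA proteins, with a median of -0.03, a mean of 0.04 and a camera direction of up, did not pass (adjusted p = 0.776). In all, 6797 genes changed, 2987 higher and 3810 lower, 487 by at least 2-fold, and 10752 with the replicate block and 2249 with median centring. The share that was higher, 43.9%, was 26.4% with median centring, and probes changed in opposite directions in 5 genes.

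Against untreated seedlings, the hemoglobin gene Os03g0234100 rose after 1 day of starvation by 2.13 (SE 0.40, adjusted p = 0.0149) and an Ole e 1 allergen and extensin domain gene, Os10g0546100, by 1.80 (SE 0.34, adjusted p = 0.0155). The peroxidases Os07g0638900 and Os07g0638800 each rose by 1.80 (SE 0.35) and the dehydrin Os11g0454200 by 1.77 (SE 0.30, at least 3.39-fold; adjusted p = 0.0905 with the slide block). The F-box genes Os06g0594400 and Os02g0671100 fell by 1.87 and 1.47, the DnaJ gene Os06g0716100 by 1.36, an auxin-induced gene, Os09g0545300, by 1.35, and Os11g0444700 by 1.09, none of which passed with the slide block. After 5 days the purple acid phosphatase Os11g0151700 had risen by 2.52 (SE 0.41, adjusted p = 0.00504; adjusted p = 0.0807 with the slide block) and the Ids4-like gene Os06g0603600 by 2.51 (SE 0.19, adjusted p = 5.92e-05). The glycosyl transferase Os01g0142300 had risen by 2.51 (SE 0.26), the SPX gene Os02g0202200 by 2.08 (SE 0.27) and the thionin Os06g0514100 by 1.95 (SE 0.39). The nicotianamine aminotransferase gene Os02g0306400area fell by 2.12 (SE 0.42, adjusted p = 0.0139). Os02g0671100, the P450 gene Os06g0641500, the lipolytic enzyme Os03g0365800 and the universal stress protein Os01g0303800 fell by 1.51, 1.32, 1.28 and 1.23, the last 4 not with the slide block. After 10 days Os04g0423400 had risen by 5.05 (SE 0.32, adjusted p = 8.08e-07), Os07g0614700 by 4.35, Os08g0299400 by 4.34, the O-methyltransferase Os11g0306400 by 4.26 and Os11g0151700 by 4.10. The nicotianamine synthase genes fell by 3.31 and 3.02, aldolase Os08g0120600 by 3.20, the phosphofructokinase gene Os05g0194900 by 2.95 and the metallothionein Os12g0568200 by 2.50, and none of these 10 genes passed with the slide block. By day 10 the PHT1 median was 1.58 with 5 rises, 9 purple acid phosphatases rose, and iron acquisition genes had a median of -0.44 with 6 falls and 1 rise. Over all genes 0 rose and 1 fell in this comparison with the slide block.

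In all, 988 genes differed between starvation and untreated seedlings on day 1 (638 higher, 350 lower), 756 on day 5 (248 and 508) and 7087 on day 10 (3837 and 3250). Such differences can also hold effects of the move to liquid medium and of age, which were not separated from starvation. The counts were 3933, 2293 and 10430 with the replicate block and 185, 199 and 1 with the slide block. Against untreated seedlings the replicate block takes the spread between numbers out of the error but not out of the group mean. Its larger counts therefore leave out the spread between the untreated samples. Leaving out any 1 array gave 3 to 442 on day 1 and 78 to 226 on day 5, and 4198 to 6294 on day 10, where replicates 1 and 3 moved it. With median centring they were 9, 10466 and 2467. The share that was higher was 64.6%, 32.8% and 54.1%. On days 1 and 10 it was 100% and 81.7% with median centring, and on day 5 it was 51.1% with the processed signals and 57.3% without background correction, while median centring moved the median of all genes by -0.14.

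Sufficient phosphate against untreated seedlings asked which transcripts changed on medium that held phosphate. On day 1 IRT1 rose by 2.19 (SE 0.41, adjusted p = 0.0121; adjusted p = 0.051 with the slide block), the sugar transporter Os04g0453300 by 1.65 (SE 0.22) and the potassium channel Os01g0648000 by 1.62 (SE 0.24). The allergen family gene Os10g0555700 rose by 1.52 (SE 0.15) and the nodule-specific protein gene Os12g0484600 by 1.48 (SE 0.22; adjusted p = 0.0831 with the slide block). Allyl alcohol dehydrogenase Os12g0227400 fell by 2.79, Os01g0127000 by 2.31, the HKT gene Os06g0701700 by 2.23, Os04g0506800 by 2.19 and the phosphate-induced protein gene Os02g0756600 by 2.17, with Os01g0127000 and Os06g0701700 not passing with the slide block. On day 5 IRT1 rose by 4.26 (SE 0.41, adjusted p = 6.29e-05), Os02g0650300 by 4.16 (SE 0.49, adjusted p = 0.000213), Os01g0871600 by 3.99 (SE 0.51) and the nicotianamine synthase genes by 3.27 (SE 0.83) and 3.03 (SE 0.80). The multicopper oxidase Os01g0127000 fell by 3.51, the P450 genes Os11g0138300 and Os02g0601500 by 2.68 and 2.64, alternative oxidase Os02g0318100 by 2.63 and aldolase Os08g0120600 by 2.46, the last 3 not with the slide block. On day 10 Os02g0650300 rose by 4.16 (SE 0.49, adjusted p = 7.93e-05), Os01g0871600 by 3.31 (SE 0.51) and the MtN3-like gene Os03g0347500 by 3.16 (SE 0.34). IRT1 rose by 2.88 (SE 0.41) and nicotianamine synthase Os03g0307200 by 2.88 (SE 0.83), both not with the slide block. The defence gene PBZ1, Os12g0555500, fell by 4.04 (SE 1.19; adjusted p = 0.12 with the slide block), and Nodulin 21 stood at -4.00. The early light-inducible protein Os07g0178700 stood at -3.83, Os01g0127000 at -3.74 and the P450 gene Os04g0178400 at -3.63. The iron acquisition list had 11 rises on day 5 and 11 on day 10, with medians of 2.14 and 1.88, and the iron storage list had medians of -0.50 and -0.68 with 3 falls each.

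In all, 1026 genes differed between sufficient phosphate and untreated seedlings on day 1 (543 higher, 483 lower), 4959 on day 5 (2742 and 2217) and 8168 on day 10 (4532 and 3636). Effects of the move to liquid medium and of age were not separated here either. The counts were 3987 and 8890 on days 1 and 5 with the replicate block, and 107 on day 1 and 2543 on day 10 with the slide block. Those with the replicate block again leave out the spread between the untreated samples. Leaving out 1 array gave 86 to 434, 988 to 3925 and 4851 to 7360, and median centring gave 26, 706 and 1802. The share that was higher on days 5 and 10, 55.3% and 55.5%, was 87.0% and 81.5% with median centring.

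Tests of the change in the starvation effect asked whether starvation and sufficient phosphate differed more on one day than on another. From day 1 to day 10 the effect rose for the stress-induced gene Os04g0423400, by 4.55 (SE 0.63, adjusted p = 0.006), and the early light-inducible proteins Os07g0178700 and Os07g0178800, by 4.43 (SE 0.75) and 4.28 (SE 0.67). It also rose for the SPX gene Os07g0614700, by 4.12 (SE 0.94, adjusted p = 0.0471), and the transferase Os06g0185500, by 3.70 (SE 0.68). It fell for the oligopeptide transporter Os02g0650300, which changed by -4.76 (SE 0.98, adjusted p = 0.0324), and the MtN3-like gene Os03g0347500, by -4.44 (SE 0.68, adjusted p = 0.0102). It was lower too for the antiporter Os11g0134900 at -3.91 (SE 0.86), Os11g0444700 at -3.01 (SE 0.57) and the F-box gene Os02g0630000 at -2.88 (SE 0.52). Of these 10 only Os03g0347500 passed with the slide block (adjusted p = 0.039). In all, 311 genes changed in effect from day 1 to day 10 (126 higher, 185 lower, 1886 with the replicate block, 44 with the slide block). It was 5 with replicates 1 and 3 of day 10 averaged in both groups and 60 to 1054 without any 1 array. There was 1 from day 1 to day 5 (37 and 0 with these blocks) and 2 from day 5 to day 10 (588 and 1, and 2 to 435 without 1 array). The gene of the first interval was Os11g0129600 at -1.55 (SE 0.19, adjusted p = 0.0202). Those of the second were the DYW9 protein gene Os03g0767700 at -2.45 (SE 0.27, adjusted p = 0.00321) and a probe for the microRNA osa-miR169b at -1.53 (SE 0.17, adjusted p = 0.00321). None of the 3 passed with the slide block (adjusted p = 0.078, 0.365 and 0.365). At unadjusted p below 0.05 there were 912 genes for day 1 to 5 and 814 with the slide block. The share that was higher from day 1 to 10, 40.5%, was 30% with median centring, which moved the median of all genes by -0.28 for day 1 to 5 and 0.36 for day 5 to 10.

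Within starvation, Os04g0423400 rose from day 1 to day 10 by 4.77 (SE 0.45, adjusted p = 0.000274) and the galactolipid synthase Os08g0299400 by 4.58 (SE 0.82). The SPX genes Os07g0614700 and Os03g0406100 rose by 4.17 (SE 0.66) and 3.64 (SE 0.65), and the O-methyltransferase Os11g0306400 by 3.58 (SE 0.84). The metallothionein Os12g0570700 fell by 3.69 (SE 0.84) and the phosphofructokinase gene Os05g0194900 by 3.09 (SE 0.57). The nitrogen genes for glutamine synthetase Os03g0223400, NADH glutamate synthase Os01g0681900 and the ammonium transporter Os02g0620600 stood at -2.26 (SE 0.32), -2.09 (SE 0.36) and -2.00 (SE 0.40). Within sufficient phosphate Os02g0650300 rose by 4.24 (SE 0.69, adjusted p = 0.00833), Os01g0871600 by 3.12, the antiporters Os12g0132500 and Os11g0134900 by 3.10 and 3.01, and Os03g0347500 by 2.78. The early light-inducible proteins Os07g0178700 and Os07g0178800 fell by 4.34 (SE 0.53, adjusted p = 0.00144) and 3.96 (SE 0.48, adjusted p = 0.00132). The P450 gene Os04g0178400 stood at -3.18, the deoxyxylulose phosphate synthase gene Os07g0190000 at -2.97 and the pathogenesis-related gene Os07g0129300 at -2.97. In all, 470 genes changed within starvation (328 higher, 142 lower) and 1096 within sufficient phosphate (804 and 292), against 1459 and 5161 with the replicate block. Leaving out 1 array gave 126 to 790 and 61 to 2760. By limma with the slide block the counts were 0 and 0, with 974 and 3113 genes at unadjusted p below 0.05. The median SE over genes went from 0.137 to 0.289 and 0.232, while Os04g0423400 stood at 5.05 (SE 1.21) within starvation and Os07g0178700 at -4.32 (SE 1.08) within sufficient phosphate, so for these genes the call ended with the wider spread. Over all genes the log2 values without and with the block correlated at 0.729 and 0.855. Day 1 and day 10 arrays shared no slide, so time and slide were confounded in both comparisons. The values with the block depended on the single day 5 array that joined their slides, and a slide effect in these counts is not excluded.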

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

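Of the tests in this part, those on the replicate number as a block, on averaged replicates and on splits that mix the day 10 groups or part every pair were chosen only after the results they bear on were seen. The results below were singled out because the starvation effect itself differed between days by the limma test.

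From day 1 to day 10 the effect changed for 311 genes. The stress-induced gene Os04g0423400 gained 4.55, with differences of 0.55, 1.58 and 5.10 on days 1, 5 and 10. The early light-inducible protein genes Os07g0178700 and Os07g0178800 gained 4.43 and 4.28, from -0.61 and -0.42 on day 1. The SPX gene Os07g0614700 gained 4.12 and the transferase gene Os06g0185500 gained 3.70. The oligopeptide transporter gene Os02g0650300 changed by -4.76, with differences of -1.61, -5.33 and -6.37 on the 3 days, and the MtN3-like gene Os03g0347500 changed by -4.44. The antiporter gene Os11g0134900 changed by -3.91, Os11g0444700 by -3.01 and the F-box gene Os02g0630000 by -2.88. From day 1 to day 5 the effect changed for 1 gene, Os11g0129600, by -1.55, and its differences on the 3 days were 0.03, -1.52 and -0.84. From day 5 to day 10 it changed for 2 genes, the DYW9 protein gene Os03g0767700 by -2.45 and the osa-miR169b probe by -1.53.

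Other splits of the same arrays, with treatments exchanged at random within each day, were counted for each of these results. As many genes as the real count were reached in 7 of 100 splits for day 1 to 10, and the highest other split gave 5450 genes. Of the 6 other splits that reached it 5 kept the real grouping of day 10, and with it the real difference of that day, so that they do not measure chance. Of the 92 splits that mixed the day 10 groups 1 reached it, with 695 genes, and the highest of the 5 other splits that part every pair of replicates gave 14. These splits leave open whether chance is excluded for the 311 genes, which became 5 with replicates 1 and 3 of day 10 averaged in both groups and 60 to 1054 without any 1 array. Without 1 array the day 5 to 10 count was 2 to 435. The share was 2 of 100 for day 1 to 5, with 183 genes in the highest other split, and 4 of 100 for day 5 to 10, with 3 genes in the highest other split. For the mean of days it was 1 of 100, with 6797 genes in the real split and 2293 in the highest other. Most drawn splits put both arrays of a replicate pair in 1 group, which can widen the spread and lower their counts. The 5 other splits that part every pair gave at most 4 genes for the mean of days. They gave at most 0 for day 1 to 5 and 1 for day 5 to 10. Splits that part every pair, as the real one does, are too few for a share under 0.05. So are the splits of 3 arrays against 3. In each of them the real split was the only 1 of 10 to reach its count, with 7 genes against 0 in the highest other on day 1, 559 against 0 on day 5, 6216 against 361 on day 10, 470 against 0 for starvation on day 10 against day 1, and 1096 against 0 for sufficient phosphate on day 10 against day 1. Among the 4 day 10 splits that part every pair of replicates the highest other count was 0.

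More genes differed between starvation and sufficient phosphate on day 10 than on days 1 and 5. A slide or scan difference on day 10 could have raised that count, since all starvation arrays lay on slide 4. The 2808 genes called from replicates 2 and 3 alone had a median difference in the called direction of 0.772 in replicate 1, whose arrays share slide 4 (quartiles 0.467 and 1.26), and 98.6% of them had the same direction there against 80.2% of other genes, which excludes the slide as the whole cause. A single untreated RNA for each number could have hidden genes on the earlier days, but with the number as a block day 1 gave 33 genes against 10113 on day 10, so this is excluded as the whole cause too. With replicates 1 and 3 of day 10 averaged in both groups day 10 still gave 2765 genes. A growing effect of starvation with time and a change in the sufficient seedlings both remain open. Against untreated seedlings 4959 genes differed under sufficient phosphate on day 5 and 8168 on day 10, and 756 and 7087 differed under starvation.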

How the results depend on the processing

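The settings that left out both day 10 arrays of replicate 2, averaged day 10 replicates 1 and 3 in the sufficient group or in both, used slide 4 alone, joined the replicate and slide blocks, or put the slide block in the list tests were chosen after seeing the data. Strict and absent filters on dim probes, between-array quantile scaling, the mean of all probes, outlier spots kept and a trended robust variance left every gene count within 1.5 times its value. Over all planned settings 173 gene counts stayed within 1.5 times and 123 moved. List results kept their side in 1392 cases, weakened in 112, strengthened in 60 and reversed in 4, and named genes reversed in 2. Of the 377 calls of named genes 232 were kept with median centring and 250 with the slide block, and 154 of 259 with only the arrays compared. Leaving out 1 array kept at the least 134 of 173. The replicate block ended no call of a gene, and beyond the values given in the results it changed no call of a list. The cause was not tested for any change below unless stated.

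With the software's processed signals, starvation against untreated seedlings on day 5 gave 2873 genes, the change of effect gave 3 genes for day 1 to 5 and 1 for day 5 to 10, and 11 lists passed on day 5. The deposited log ratios gave 2872, 3 and 1. Without background correction starvation against sufficient phosphate on day 5 gave 913 genes and starvation against untreated on day 5 gave 3080. Median centring gave 0, 4026, 1293 and 2249 genes for starvation against sufficient on days 1, 5, 10 and their mean. It gave 9, 10466 and 2467 for starvation against untreated and 26, 706 and 1802 for sufficient against untreated. It gave 0 and 20 for the change of effect from day 1 to 5 and to 10, and 114 and 22 for day 10 against day 1 within starvation and sufficient phosphate. By limma the zero counts stood beside 475 genes at unadjusted p below 0.05 on day 1 and 3767 for the change to day 5. Median centring leaves trends with intensity in place by construction. Reversed under it were the phosphofructokinase gene Os06g0247500 at -0.21 and expansin 4, Os04g0583500, at -0.17 on day 5, and the gene list of cytosolic ribosomal proteins on day 1 (adjusted p = 0.0253) and day 5 (adjusted p = 0.000621). That list, not past the threshold on day 1, also reversed without starvation replicate 3 of day 1 (adjusted p = 0.00297) and without sufficient replicate 2 of day 1 (adjusted p = 7.25e-05). Leaving out 1 array gave it adjusted p values from 2.5e-07 (sufficient replicate 3) to 0.906 (sufficient replicate 1).

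The replicate block gave 33, 2549, 10113 and 10752 genes for starvation against sufficient. On days 1 and 5 it gave 3933 and 2293 for starvation against untreated and 3987 and 8890 for sufficient against untreated. It also gave 37, 588 and 1886 for the changes of effect from day 1 to 5, 5 to 10 and 1 to 10, and 1459 and 5161 for day 10 against day 1. The replicate block removes the shared deviation of arrays with 1 number by construction. Against untreated seedlings its counts therefore leave out the spread between the untreated samples. The slide block gave 104 and 3380 for starvation against sufficient on days 5 and 10, 185, 199 and 1 for starvation against untreated, and 107 and 2543 for sufficient against untreated on days 1 and 10. It gave 0, 1 and 44 for the changes of effect and 0 and 0 for day 10 against day 1. By limma 814, 974 and 3113 genes at unadjusted p below 0.05 stood beside the zero counts. For the mean of days 7 lists passed with it. Both blocks together gave 30, 332 and 2931 for days 1, 5 and 10, 8 for starvation against untreated on day 10, and 571 and 4663 for sufficient against untreated on days 1 and 10. They gave 14 and 100 for the changes to day 5 and from day 1 to 10, and 0 and 2 for day 10 against day 1, the zero with 1488 genes at unadjusted p below 0.05 by limma. In the main fit all groups shared 1 spread, although red SDs between replicates reached 0.497 on day 10 and 0.410 on days 1 and 5. Fitting only the arrays compared let the spread differ between comparisons and left fewer arrays to estimate it. This fit gave 0 and 2851 on days 1 and 10. It gave 0, 0 and 1690 for starvation against untreated, 0, 635 and 838 for sufficient against untreated, 0, 0 and 125 for the changes of effect, and 22 and 15 for day 10 against day 1. By limma the zero counts stood beside 1804, 4320, 4350, 3262, 1212 and 3053 genes at unadjusted p below 0.05, in that order. An estimated correlation in camera left 0, 0, 0 and 0 lists on days 1, 5, 10 and their mean, against 10, 7, 14 and 11 with the preset one. Without both day 10 arrays of replicate 2 the counts were 660 and 1428 for the changes from day 5 and from day 1 to day 10, and 1190 and 2536 for day 10 against day 1. Averaging sufficient replicates 1 and 3 of day 10, which were alike in the red channel, gave 4581 for sufficient against untreated, 107 for the change from day 1 to 10 and 108 for day 10 against day 1. Averaging them in both groups gave 2765 genes on day 10, of which 2763 were shared, 3994 and 4606 for starvation and sufficient against untreated, 5 for the change from day 1 to 10, and 124 and 87 for day 10 against day 1 within starvation and sufficient phosphate. Slide 4 alone gave 2659 genes on day 10, of which 2360 were shared.

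Leaving out 1 array at a time gave 2 to 8 genes on day 1 (moved by every array but starvation replicate 3) and 91 to 824 on day 5 (by every array but sufficient replicate 3). It gave 4045 to 6263 on day 10 (by starvation replicate 3) and 5317 to 7377 for the mean of days (by none). Against untreated seedlings starvation gave 3 to 442, 78 to 226 (by every array on both days) and 4198 to 6294 (by replicates 1 and 3). Sufficient phosphate gave 86 to 434 (by every array), 988 to 3925 (by replicates 1 and 2) and 4851 to 7360 (by replicates 1 and 3). The changes of effect gave 0 to 23 for day 1 to 5 (by every array but starvation replicate 1 of day 5), 2 to 435 for day 5 to 10 (by starvation replicate 1 of day 5 and both replicates 2 of day 10) and 60 to 1054 for day 1 to 10 (by every array). Day 10 against day 1 gave 126 to 790 within starvation (by every array but replicate 3 of day 1) and 61 to 2760 within sufficient phosphate (by every array). Lists that passed numbered 4 to 16 on day 1 (by starvation replicates 2 and 3 and sufficient replicates 1 and 2) and 6 to 12 on day 5 (by starvation replicate 2). They numbered 12 to 15 on day 10 (by none) and 6 to 14 for the mean of days (by starvation replicate 3 and sufficient replicate 2 of day 1 and sufficient replicate 2 of day 10). On day 10 the lists that no longer passed were cytosolic ribosomal proteins (adjusted p = 0.066) and cell wall loosening (adjusted p = 0.0793) without starvation replicate 2, and PHT1 transporters without starvation replicate 3 (adjusted p = 0.0648). Without sufficient replicate 2 they were PHT1 transporters and phenylpropanoids (adjusted p = 0.172 each) and purple acid phosphatases (adjusted p = 0.0667). Without sufficient replicate 3 the cytosolic ribosomal list did not pass (adjusted p = 0.0952), nor did chlorophyll synthesis without replicate 1 or 3. The lowest count for day 1 to 5 was 0 by limma, with 569 to 1908 genes at unadjusted p below 0.05. Signal over background limits the probes that could be tested, 35391 of 42418.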

Other observations

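The groups of genes in this part, and the tests of the iron pattern and of the replicate numbers, were chosen only after the results were seen, so no p value is given for the 6 groups examined.

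Probes for precursors of the microRNA miR169, a regulator of NF-Y transcription factors, were lower under starvation: 11 of 14 fell on day 10, with a median of -2.10, and 11 fell with the slide block. On day 5 their median was -0.91 and 2 fell, 9 with the replicate block. Genes grouped as methionine recycling had 6 falls among 14 on day 5 and 7 falls and 1 rise on day 10. Among them Os04g0669800 stood at -2.35 on day 5 and -2.10 on day 10, and Os12g0589100 at -1.90 and -1.24. The 14 include Os04g0306400, a ribose 5-phosphate isomerase family gene, at -3.61 and -3.49.

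DUF581 genes had 12 rises and 1 fall among 18 on day 10, 7 and 0 with the slide block, with a median of 0.92. Fasciclin domain genes had 11 rises among 18, with a median of 0.70. Proteasome subunits had 9 rises and 1 fall among 54, against 2914 and 3302 among all 24515 genes. Their counts were 20 and 3 with the replicate block and 3 and 1 with the slide block. Germin-like genes had 2 falls among 16 on day 10, 6 with the replicate block and 5 with the slide block. On day 5 their median was -1.25 with 0 past the threshold by limma, and 3 fell with the replicate block.

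Iron acquisition genes were lower under starvation than under sufficient phosphate on days 5 and 10. A slide difference is excluded, since the median of the list closest to 0 within a slide was -1.76. The root markers showed no large common fall, with a median of -0.24 and single values from -0.68 to 0.29 on day 10. On day 5 they scattered from -0.90 to 1.21. They are few and include transporters of metals and ammonium, which may themselves respond to the medium. They therefore do not settle whether a smaller share of root tissue under starvation contributed. An iron shortage in the sufficient seedlings may have contributed: against untreated seedlings on day 10 their iron acquisition list had a median of 1.88 and their iron storage list a median of -0.68, values that explanation needs. Iron content was not measured, and the dye was not swapped in those comparisons.

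Arrays with the same replicate number deviated from their group means together. A shared slide is excluded as the whole cause, since the 28 pairs of the same number on different slides had correlations across genes of at least 0.115. A single untreated RNA for each number is not excluded by the green channels, where the SD of the log2 difference was at most 0.202 between arrays of the same number and at least 0.321 between arrays of different numbers. Green channel deviations of the same number had correlations across genes of 0.648 to 0.972, with a median of 0.914. Between different numbers the green median was -0.494. A single untreated RNA for each number needs such values. Treated seedlings of 1 number might also share a batch, since red channel deviations of the same number had a median correlation across genes of 0.146, with a range of -0.451 to 0.649. That red median was well below the green one. No biological explanation was tested for this pattern.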
